A study of Mus musculus with 96 samples.

How the data were processed

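The data are RNA-seq read counts from small pools of nuclei sorted from mouse visual cortex by flow cytometry. Per the labels, each library was made from 50 to 100 nuclei, with cDNA primed on poly(A) tails and extended by template switching, 17 cycles of PCR, tagmentation, and synthetic spike-in RNAs. This chemistry does not mark the strand, so reads from overlapping or antisense genes cannot be told apart. Reads amplified by PCR without molecular identifiers are not independent molecules, so every floor given for a count of 0 covers counting error only.

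The deposited table holds raw counts per gene and library, and it is the only file used. The authors' notes name cutadapt 1.18, STAR 2.5.3a and HOMER 4.9.1 and the mm10 build, and state neither the annotation release nor the strand setting. All values were checked to be whole numbers, with totals of 1559883 to 9122515 per library. Of 55335 gene identifiers, 55154 were matched to a GENCODE annotation of the same build for symbols, positions and lengths. The 181 unmatched identifiers held 0.0225% of the counts and were left unnamed. All 96 libraries were used.

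The libraries fall into 24 groups, made of 3 lines, 2 viruses, 2 light conditions and 2 sorted fractions. Each of the 12 conditions gave 3 to 5 replicates of VIP-positive nuclei and as many of total nuclei. The labels number the replicates but do not state that a VIP library and a total library of the same number came from 1 animal. Their sex labels matched in 48 of 48 pairs, and the pairs are taken as 1 animal only where that is said. Levels of sex-linked genes matched the sex label in 94 of 96 libraries. No library fell below 0.5 of the median number of detected genes of its fraction, so leaving out such libraries, which had been foreseen, changes nothing. No 2 libraries of a group were duplicates (148 pairs checked).

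Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM library sizes, the default filter on low counts, robust estimates of spread and 1 coefficient per group. VIP nuclei (48 libraries, 20585 genes tested) and total nuclei (48 libraries, 21213 genes) were fitted separately, and comparisons between them used a fit of all 96 libraries (22926 genes). P-values were adjusted by the Benjamini-Hochberg method and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change is the fold change divided by the square root of F, an approximation adopted after the first results were seen. Levels are counts per 1000000 (CPM) on TMM library sizes, given as mean ± SD. The biological coefficient of variation was 0.815 in VIP and 0.679 in total nuclei, so most single genes can be called only at large changes. In a test on simulated counts with the real group sizes, the light comparison averaged over 3 lines in VIP nuclei recovered 22 of 100 genes with a 2-fold change, and 21 of 35 above 20 CPM. It recovered 56 of 100 with a 4-fold change. The comparison of 4 Cre with 4 dCre libraries of line E123 recovered 3 of 100 genes with a 2-fold change and 26 of 100 with a 4-fold change.

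Igf1 was tested on its own in each of 24 contrasts, 12 of Cre with dCre and 12 of light with dark, with an exact two-sided permutation test of the mean log2(CPM + 1), adjusted over the 24. The edgeR log2 fold change, its SE and its p adjusted over the same 24 contrasts stand beside it; that second adjustment was added after seeing the data. Differences of the Cre effect on Igf1 between lines were tested in edgeR and adjusted over 6 tests. They were also tested by permutation of the virus labels within line and light condition, adjusted in the same way. That permutation assumes no Cre effect in either line, so it does not test equal effects exactly.

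The tests, the rule for named genes and 24 gene lists were fixed before the data were examined. The lists are rapid immediate-early genes, activity-regulated effector genes, markers of VIP, all GABAergic, parvalbumin, somatostatin and Lamp5 or Sncg interneurons, of excitatory neurons, astrocytes, oligodendrocyte lineage, microglia and endothelial or mural cells, IGF1 signalling genes, genes around Igf1 on chromosome 10, inhibitory synapse genes, excitatory synapse genes, voltage-gated ion channels, circadian clock genes, MAPK phosphatases and feedback regulators, p53 target genes, interferon response genes, heat-shock and dissociation-stress genes, mitochondrially encoded genes and nuclear-retained long noncoding RNAs. The lists overlap: Igf1, for example, is in the effector, IGF1 signalling and chromosome 10 lists. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. In every comparison the named genes are Igf1, Vip, Fos and Npas4, up to 10 genes in each direction with the smallest p among those past the threshold, and up to 4 members of each list past the threshold. Predicted genes, unnamed loci and, for the 10 in each direction, genes under 5 CPM in both groups were excluded. The text gives a part of these names.

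A length index was computed per library as the mean log2 CPM of protein-coding genes over 100 kb minus that of genes under 10 kb. Alternatives fixed before the data were examined were RLE size factors, no filter and a stricter filter (10 counts in 0.5 of the libraries), DESeq2 1.42.0, limma-voom with quality weights, a sex covariate, a replicate block, fits of only the groups compared, leaving out each library in turn, and for Igf1 a pseudocount of 0.1 or 5. Chosen after seeing the data were the length index as a covariate, leaving out 2 animals of the E1 dCre dark group, 4 animals of the E1 and E123 dCre dark groups, or 1 animal whose sex label did not match, and the comparisons that average Cre animals over lines. Up to 100 other splits of the samples were refitted for each comparison, keeping the trend of the spread with expression from the real grouping.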

Results

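The libraries measure nuclear RNA in the visual cortex of adult mice of 3 lines, E1, E23 and E123, in which enhancers of Igf1 (insulin-like growth factor 1) are flanked by sites that the recombinase Cre cuts. A virus gave either Cre or its inactive form dCre to VIP cells, cortical interneurons that make vasoactive intestinal peptide. It was injected at 55 to 60 days of age, the mice went into darkness 3 days later for 10 to 12 days, and some then saw light for 1 h. VIP nuclei and total nuclei, a sample of all cells, were sorted and sequenced separately. For each fraction, line E1 gave 5 light and 3 dark dCre replicates and 4 light and 5 dark Cre replicates. Line E23 gave 4 replicates of each condition, and line E123 gave 4 of each except 3 of dark Cre. VIP libraries held 1559883 to 9122515 counts and a median of 19124 detected genes, and total libraries 1881731 to 8972526 counts and 20742 genes. Gene counts do not cover the deleted enhancers, so the deletion itself was not measured.

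Libraries differed in the balance of long and short genes, measured as the mean log2 CPM of long minus short protein-coding genes. This length index was 3.96 ± 1.21 (SD, n = 3) in dark dCre VIP nuclei of E1 and 3.83 ± 0.848 (n = 4) in those of E123. Light dCre VIP nuclei of E123 stood at 3.23 ± 0.223 (n = 4), and the other 9 VIP groups averaged 1.64 to 2.70. In the E1 dark dCre group, replicates 1 and 2 had indices of 4.67 and 4.64 in VIP nuclei and 3.88 and 4.03 in total nuclei, against 2.56 and 2.11 in replicate 3. Replicates 1 and 2 of the E123 dark dCre group were also high, with 4.56 and 4.52 in VIP nuclei and 4.39 and 3.93 in total nuclei.

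**Figure D1:**
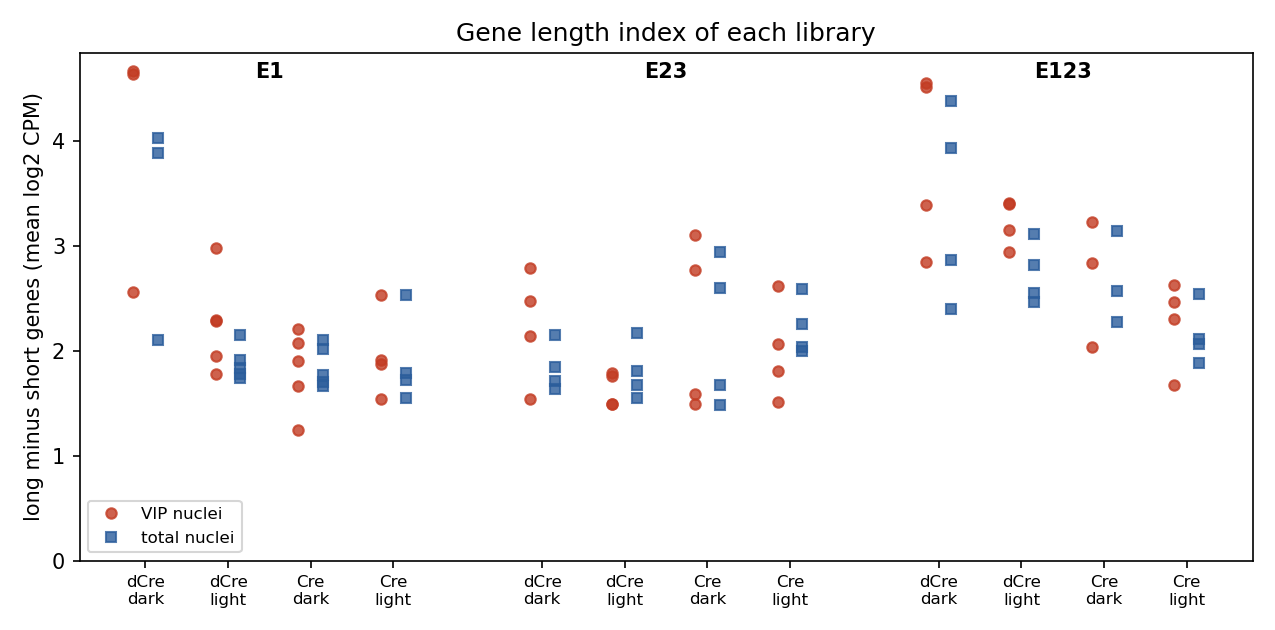
The gene length index (mean log2 CPM of long minus short protein-coding genes) of every library, by line, virus and light condition, with circles for VIP nuclei and squares for total nuclei. The dark dCre groups of E1 and E123 hold the highest values, up to 4.67.

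Whether loss of the enhancers lowers Igf1, a secreted growth factor, in VIP cells was tested by comparing Cre with dCre in each line and light condition. Mean Igf1 (ENSMUSG00000020053; chromosome 10, 87858265 to 87937042, plus strand, mm10) was lower with Cre in 6 of 6 comparisons of VIP nuclei. After light, E123 VIP nuclei held 300.5 ± 47.3 CPM with Cre (SD, n = 4) and 705.4 ± 84.8 with dCre (n = 4), a fitted 42.6% of the control. The E1 line after light held 482.4 ± 125 with Cre (n = 4) and 830.1 ± 111 with dCre (n = 5), or 58.1%. In both, 4 of 4 Cre libraries lay below every dCre library. In the dark, E1 held 397.1 ± 45.2 (n = 5) and 594.4 ± 77 (n = 3), or 66.8%, with 5 of 5 Cre libraries below every dCre library, and E123 held 295.3 ± 56.7 (n = 3) and 415.7 ± 126 (n = 4), or 71.1%. The E23 line stood at 82.3% in the dark (491.2 ± 216 against 596.3 ± 73.8) and 82.1% after light (621.4 ± 121 against 757 ± 122; n = 4 each). Vip itself differed between Cre and dCre by −0.0127 to 2.10 (log2) in these comparisons.

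The exact two-sided permutation test gave p = 0.0286 for E123 and 0.00794 for E1 after light and 0.0179 for E1 in the dark, each the smallest its group sizes allow. It gave 0.229 for E123 in the dark and 0.257 and 0.171 for E23 in the dark and after light. Adjusted over the 24 Igf1 contrasts, no permutation p was under 0.137. Alone, no contrast could pass that adjustment even at the smallest p its group sizes allow, so the adjusted permutation test decides little. In edgeR, the change was −1.23 ± 0.234 (log2 ± SE) for E123 and −0.78 ± 0.222 for E1 after light, with p adjusted over the 24 contrasts of 6.37e-05 and 0.0105. The adjusted p of E1 after light became 0.0877 without Cre light replicate 3. The dark changes were −0.58 ± 0.235 in E1 (adjusted p = 0.0981), −0.49 ± 0.252 in E123 (0.222) and −0.28 ± 0.231 in E23 (0.5). Without dark Cre replicate 4 of E23, which held 806.3 CPM, the E23 dark change was −0.63 with an adjusted p of 0.0432. Scaling by total counts alone brought the difference in mean log2(CPM + 1) from −0.58 to −0.21 in E1 and from −0.46 to −0.30 in E123 in the dark. In total nuclei Igf1 averaged 3.56 to 22.5 CPM per group, and SEs of 1.12 to 1.25 on its Cre effects mean that the changes seen in VIP nuclei were not detectable there.

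**Figure D2:**
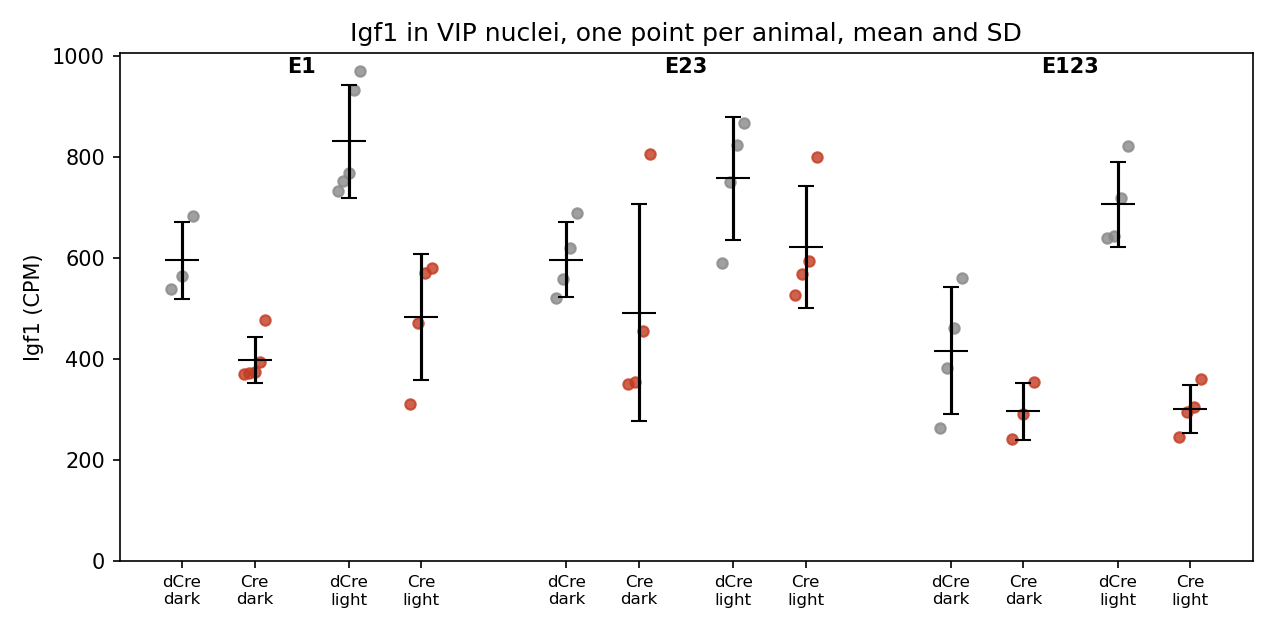
Igf1 in VIP nuclei in counts per 1000000 (CPM), 1 point per library, by line, virus and light condition, with the mean and SD of each group. After light, the 4 Cre libraries of E123 lie between 244.3 and 359.7 CPM, below the 4 dCre libraries at 639.2 to 820.2 CPM.

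How the Cre effect on Igf1 differed between lines was tested within each light condition. After light the Igf1 change was 0.95 ± 0.327 higher (log2 ± SE) in E23 than in E123, with an edgeR p of 0.0329 adjusted over the 6 tests between lines and a permutation p of 0.0641 (0.384 adjusted). The other 5 differences had adjusted p of 0.328 to 0.797. The edgeR call between E23 and E123 was lost with 7 of the 16 libraries left out in turn: E123 dCre light replicates 1 (0.0508) and 3 (0.0828), E123 Cre light replicates 1 (0.0915) and 3 (0.0531), E23 dCre light replicates 1 (0.0988) and 2 (0.0532) and E23 Cre light replicate 1 (0.121). It was also lost with the length index as a covariate (0.73, adjusted p = 0.137) and without a filter on low counts (0.94, adjusted p = 0.0721).

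Whether light raises Igf1 was tested in the same libraries. In dCre VIP nuclei, mean Igf1 was higher after light in 3 of 3 lines, by 0.48 ± 0.242 (log2 ± SE) in E1, 0.34 ± 0.231 in E23 and 0.76 ± 0.232 in E123. Scaling by total counts alone brought the difference in mean log2(CPM + 1) in E1 from 0.48 to 0.82. Averaged over the lines Igf1 rose by 0.53 ± 0.136, from 530.1 ± 126 CPM (n = 11) to 769.2 ± 112 (n = 13), with an edgeR p of 0.0146 adjusted over all genes. In Cre VIP nuclei it differed by 0.28 in E1, 0.34 in E23 and 0.0254 in E123, with exact permutation p of 0.27, 0.229 and 0.686. The light response of Igf1 with Cre minus that with dCre was −0.74 ± 0.339 in E123 (unadjusted edgeR p = 0.0339, permutation p = 0.19). In E1 it was −0.20 ± 0.324 (unadjusted edgeR p = 0.537, permutation p = 0.598). In E23 these tests gave p of 0.989 and 0.847, and no line passed in edgeR adjusted over all genes. The permutation exchanged virus labels within each light condition, so it assumes no Cre effect rather than an equal one. Among single lines, E123 dCre passed in edgeR over the 24 contrasts (adjusted p = 0.0142), but not without light replicate 3 (0.0651), dark replicate 2 (0.0589) or dark replicate 4 (0.0851). For E23 Cre the change was 0.69 without dark replicate 4 (adjusted p = 0.0273). The averaged dCre rise did not pass without E1 dark replicates 1 and 2 together (0.55, adjusted p = 0.13).

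The makeup of the sorted nuclei was compared over all 48 VIP and 48 total libraries. VIP nuclei held 123.7-fold more Vip (chromosome 10, 5639218 to 5647617; 5359 ± 3290 CPM against 44.64 ± 49.2) and 58.94-fold more Igf1 (572.8 ± 206 against 10.14 ± 8.78). Of the VIP interneuron markers, 13 of 13 were higher in VIP nuclei, among them Crh, the neuropeptide corticotropin-releasing hormone (67.86-fold), and the cannabinoid receptor Cnr1 (11.97-fold). The 10 GABAergic markers were also all higher, including Gad1, which makes GABA (548.9 ± 204 against 82.24 ± 45.2 CPM). Markers of excitatory neurons (16 of 16), the oligodendrocyte lineage (14 of 14) and microglia (11 of 11) were lower. Slc17a7, the vesicular glutamate transporter, stood at 16.11 ± 12 against 67.26 ± 17.3 CPM and the microglial receptor Csf1r at 7.716 ± 6.34 against 43.86 ± 39.1. All these markers passed over all genes and adjusted over the list alone. Camera called the 5 lists, and all but microglia stayed called with an estimated correlation (adjusted p of 1.29e-08 for VIP, 3.49e-07 for GABAergic, 1.38e-05 for excitatory and 0.033 for oligodendrocyte markers); for microglia, adjusted p = 0.0533 with an estimated correlation.

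Further lists differed between the fractions. Circadian clock genes were lower in VIP nuclei for 13 of 18 members, such as the output factor Hlf (−1.85 ± 0.157, log2 ± SE), and stayed called (adjusted p = 0.033 with an estimated correlation). The 9 mitochondrially encoded genes were higher (mt-Nd1, 0.83 ± 0.151), with an adjusted p of 0.283 with an estimated correlation. IGF1 signalling genes had 9 members higher and 4 lower of 29, with the adaptor Grb10 at 1.87 ± 0.0879 and the binding protein Igfbp6 at −2.37 ± 0.236 (adjusted p = 0.141 with an estimated correlation). Among 22 genes around Igf1 on chromosome 10, 6 were higher and 4 lower, and among 14 MAPK phosphatases and feedback regulators 1 was higher and 9 lower, with Dusp14 at −1.64 ± 0.185 (adjusted p = 0.0804 with an estimated correlation for each of these lists). Adjusted over the list alone, the counts were the same except 10 higher for IGF1 signalling and 5 lower around Igf1.

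The 14 remaining lists were not called, with members on both sides of the threshold. Immediate-early genes (6 higher and 12 lower of 29; adjusted p = 0.231), effector genes (7 and 13 of 24; 0.686), parvalbumin markers (2 and 3 of 8; 0.45), somatostatin markers (2 and 4 of 8; 0.903) and Lamp5 and Sncg markers (3 and 2 of 6; 0.178) were among them. So were astrocyte markers (0 and 4 of 10; 0.162), endothelial and mural markers (3 and 1 of 10; 0.231), inhibitory synapse genes (5 and 8 of 22; 0.686), excitatory synapse genes (9 and 9 of 25; 0.886) and ion channels (13 and 10 of 26; 0.206). The last were p53 targets (2 and 3 of 14; 0.686), interferon response genes (1 and 4 of 17; 0.206), heat-shock genes (0 and 3 of 10; 0.231) and nuclear-retained long noncoding RNAs (4 and 3 of 9; 0.125). Adjusted over the list alone, these counts were the same except 5 lower for somatostatin markers, 14 higher for ion channels, 4 lower for p53 targets and 0 higher for interferon genes. The medians and tests had opposite signs for parvalbumin markers (median −0.17, camera direction up though not called), somatostatin markers (−0.82, up) and excitatory synapse genes (−0.0143, up). In all, 8140 of 22926 genes passed, 3391 higher and 4749 lower in VIP nuclei.

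The light response of VIP nuclei was read in dCre mice, averaged over the lines (13 light and 11 dark VIP libraries). Light raised the rapid immediate-early genes, transcription factors and signalling genes that neuronal activity switches on. The nuclear receptor Nr4a1 (ENSMUSG00000023034; chromosome 15, 101254269 to 101274795) rose by 2.19 ± 0.232 (log2 ± SE), from 38.75 ± 22.2 to 176.9 ± 56.3 CPM, and the AP-1 members Fosl2 and Junb rose by 2.86 ± 0.349 and 2.87 ± 0.389. Egr1 rose by 3.11 ± 0.39, Fos by 3.12 ± 0.598 and Npas4 by 2.46 ± 0.553. Beyond transcription factors, light raised the growth factor gene Pdgfa (1.45 ± 0.239), the prohormone convertase Pcsk1 (1.25 ± 0.196), the postsynaptic scaffold Homer1 (0.93 ± 0.219) and the long noncoding RNA Mir670hg (1.43 ± 0.219). It lowered Upp2, a uridine phosphorylase (−1.17 ± 0.189), Xrcc5, a DNA end-joining factor (−1.73 ± 0.3), and the zinc finger gene Zkscan2 (−1.15 ± 0.199).

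Among the lists, 19 of 29 immediate-early genes rose (24 adjusted over the list alone), as did 14 of 24 effector genes (20 adjusted over the list alone) and 6 of 12 MAPK phosphatases and feedback regulators (9 adjusted over the list alone). Of the heat-shock genes, chaperones that many stresses induce, 7 of 10 rose (10 adjusted over the list alone), with Hsph1 at 2.08 ± 0.277 and Dnajb1 at 2.81 ± 0.41. These 4 lists stayed called with an estimated correlation (adjusted p = 4.72e-05, 0.000101, 4.72e-05 and 0.00191). Markers of other cells moved with them: camera also called upward the astrocyte (4 of 10 past the threshold, 7 adjusted over the list alone), microglia (3 of 11, and 3 adjusted over the list alone), oligodendrocyte (1 of 14, and 6 adjusted over the list alone) and excitatory neuron markers (2 of 16, and 2 adjusted over the list alone). Their adjusted p was 0.24, 0.0511, 0.24 and 0.26 with an estimated correlation. GABAergic markers (5 of 10 higher, with Gad1 at 0.85 ± 0.16), VIP markers (3 of 13), p53 targets (2 of 12) and ion channels (1 higher and 4 lower of 26) were called by camera as well. Adjusted over the list alone these were 6 higher and 1 lower, 4 and 2, 4 and 0, and 1 and 6. They had an adjusted p of 0.0511, 0.318, 0.26 and 0.271 with an estimated correlation. The list counts were not repeated without the dark dCre animals of high length index. In VIP nuclei of Cre mice over all lines, 9 of 29 immediate-early and 1 of 24 effector genes rose. Among MAPK regulators 1 of 12 passed there, and among heat-shock genes 0 of 10. Of these lists, only the heat-shock genes were not called there with an estimated correlation (adjusted p = 0.247).

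In all, 1290 of 20585 genes passed in VIP nuclei, 817 higher and 473 lower after light. Leaving out single dCre libraries gave 638 genes without E1 dark replicate 1, 615 without E1 dark replicate 2, 2476 without E1 dark replicate 3, 824 without E123 light replicate 1, 729 and 773 without E123 dark replicates 1 and 2, and 793 without E23 dark replicate 1. Without the E1 dark replicates 1 and 2, whose length index stood apart, 73 genes passed, of which 62 were among the 1290, and without those of E123 as well it was 46, of which 41 were among them. Nr4a1, Fosl2, Egr1, Junb, Hsph1, Dnajb1, Mir670hg, Pdgfa, Homer1, Upp2, Zkscan2 and Xrcc5 passed in each of these fits. Fos was 2.71 and 2.65 without the 2 and the 4 animals and did not pass (adjusted p = 0.142 and 0.266), nor did Gad1 (0.78, adjusted p = 0.0962) and Pcsk1 (0.90, adjusted p = 0.114) without the 4. With the length index as a covariate, Fos (2.42, adjusted p = 0.0711), Gad1 (0.51, 0.168), Npas4 (2.44, 0.157) and Vip (0.24, 0.748) did not pass. The change of Npas4 was 4.93 and 5.01 without the 2 and the 4 animals. Vip was higher after light by 0.95 ± 0.261 (adjusted p = 0.0242), but not past the threshold without E1 dark replicate 1 (0.0723), 2 (0.066) or both (0.64, adjusted p = 0.424).

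Within single lines the VIP light response of dCre mice was called for fewer genes in E23 and E123 than in E1. In E23, 10 genes passed (7 higher, 3 lower): Nr4a1 rose by 3.02 ± 0.402 (log2 ± SE; 229.1 ± 61.4 against 28.13 ± 14.7 CPM, n = 4 each) and Fosl2 by 3.11 ± 0.59. In E123, 2 genes passed, Fosl2 (3.37 ± 0.593, with 126.3 ± 29 against 12.29 ± 4.85 CPM, n = 4 each) and Nr4a1 (2.09 ± 0.388). With a replicate block, Nr4a1 of E123 did not pass. In E1, 860 genes passed (552 higher, 308 lower), with Egr1 at 3.99 ± 0.752 and the synaptotagmin Syt4 at 2.86 ± 0.505. Immediate-early genes were called as a list in each line, with an adjusted p of 0.022 in E1, 9.91e-05 in E23 and 0.000399 in E123 with an estimated correlation. Camera called 9, 13 and 8 of the 24 lists in E1, E23 and E123, of which 3, 4 and 5 stayed called with an estimated correlation. The 5 of E123 were immediate-early genes, effector genes, MAPK regulators, heat-shock genes and GABAergic markers. The last 4 had 0 members past the threshold, and 8, 0, 2 and 2 adjusted over the list alone, with medians of 1.16, 0.92, 1.03 and 0.81. Without E1 dark replicate 1, Egr1 (adjusted p = 0.0624) and Syt4 (0.0508) did not pass. The E1 count fell to 17 without dark replicate 1, 124 without dark replicate 2, 319 without light replicate 2 and 373 without light replicate 3, and rose to 2425 without dark replicate 3. Without both dark replicates 1 and 2 it was 0 in edgeR, in a fit where the 1 dark library left is assumed to vary like the other groups, so that few changes can be called. Egr1 was 2.78 and Syt4 2.497 there (adjusted p = 0.663 for each). The E23 count became 3, 5 and 1 without light replicates 1, 2 and 3 and 1, 1 and 4 without dark replicates 2, 3 and 4, and Nr4a1 passed there each time. Fosl2 of E23 did not pass without light replicates 1 (adjusted p = 0.0747) or 3 (0.0556) or dark replicates 2 (0.0901) or 3 (0.132). The E123 count became 0 without light replicate 1, dark replicate 1 or dark replicate 2, and 1 without dark replicate 3 or 4. There Nr4a1 did not pass without light replicates 1 (0.106) or 2 (0.0549) or dark replicates 1 to 4 (0.125, 0.128, 0.0887 and 0.0682), nor Fosl2 without light replicate 1 (0.0684) or dark replicates 1 (0.107), 2 (0.128) or 4 (0.0738).

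In total nuclei of dCre mice, the same comparison asks how the cortex as a whole responds to light. Nr4a1 rose by 2.23 ± 0.19 (log2 ± SE), from 31.18 ± 13.9 CPM (n = 11) to 147.2 ± 41.4 (n = 13), Fos by 3.44 ± 0.454 and Pcsk1 by 2.07 ± 0.213. The neurotrophin gene Bdnf rose by 1.90 ± 0.262 and its receptor Ntrk2 by 1.04 ± 0.131. So did the kinase Sik2 (1.66 ± 0.185), Homer1 (1.48 ± 0.199), the insulin receptor substrate Irs2 (1.67 ± 0.337) and Tiparp (2.68 ± 0.335). Light lowered Armc2 (−1.35 ± 0.242), the laminin gene Lama4 (−1.58 ± 0.3), Zkscan2 (−1.02 ± 0.193) and Rorb, a marker of layer 4 neurons (−0.95 ± 0.173). Of the lists, 23 of 27 immediate-early genes rose (25 adjusted over the list alone), 17 of 24 effector genes (18 adjusted over the list alone), 7 of 14 MAPK regulators such as Dusp1 (1.89 ± 0.284) and Dusp6 (2.19 ± 0.397; 9 adjusted over the list alone) and 8 of 10 heat-shock genes (8 adjusted over the list alone). These stayed called with an estimated correlation (adjusted p = 3.13e-08, 3.68e-06, 1.23e-05 and 0.00114). Astrocyte markers (1 of 10, 7 adjusted over the list alone; median 1.09) and p53 targets (3 of 12, 6 adjusted over the list alone; median 0.58) were also called, with 0.0294 and 0.0236. Ion channels had 2 members higher and 4 lower of 26 (2 and 11 adjusted over the list alone), a call with an adjusted p of 0.942 with an estimated correlation.

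Of 21213 genes, 1207 passed in total nuclei, 726 higher and 481 lower. The count was 630 without E1 dark replicate 1, 597 without E1 dark replicate 2 and 2466 without E1 dark replicate 3. Without E1 dark replicates 1 and 2 together 197 genes passed, of which 175 were among the 1207, and without those of E123 as well it was 157, of which 117 were among them. The genes named above passed in each of these fits, except Rorb, whose adjusted p was 0.056 without the 4 animals. Igf1 (−0.27 ± 0.673, log2 ± SE) and Vip (1.13 ± 0.912) did not pass in total nuclei.

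Line by line, light called 781 genes in E1 total nuclei (470 higher, 311 lower), 38 in E23 (31 and 7) and 79 in E123 (69 and 10). Nr4a1 rose by 2.54 ± 0.323 (log2 ± SE) in E23 and 2.44 ± 0.321 in E123 (n = 4 against 4 in each). Pcsk1 rose by 2.39 ± 0.361 and 2.40 ± 0.361, and these genes passed with each library left out. In E23, Bdnf rose by 2.38 ± 0.448 and Ntrk2 by 1.34 ± 0.224, and in E123 Egr1 rose by 2.93 ± 0.472, Homer1 by 1.89 ± 0.34 and Hsph1 by 1.76 ± 0.303. In E1 the ubiquitin ligase gene Rnf187 rose by 2.12 ± 0.333, from 24.7 ± 2.88 CPM (n = 3) to 107 ± 6.9 (n = 5), and passed with each single library left out. Without dark replicates 1 and 2 together, which leaves 1 dark library, it was 2.03 and did not pass (adjusted p = 0.565), nor did it with the length index as a covariate (1.04, adjusted p = 0.361). The E1 count was then 0 and 4. Hsph1 of E123 did not pass without dark replicates 1 and 2 of E1 and E123 (0.195). Immediate-early genes past the threshold numbered 9 of 27 in E1, 6 of 27 in E23 and 13 of 27 in E123, with an adjusted p of 0.0121, 1.13e-06 and 1.15e-07 with an estimated correlation. The E1 count was 6 without dark replicate 1, 4 without dark replicate 2, 2904 without dark replicate 3, 342 without light replicate 2 and 242 without light replicate 5. In E23 it was 23 and 20 without light replicates 2 and 3 and 16 and 15 without dark replicates 3 and 4. In E123 it was 49 without light replicate 1, and 37, 24 and 145 without dark replicates 1, 2 and 4.

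Whether light acts differently on VIP nuclei than on total nuclei was tested as the difference of their responses in dCre mice. Fos differed by −0.33 ± 0.698 (log2 ± SE), Npas4 by −0.0339 ± 0.691, Vip by −0.17 ± 0.903 and Igf1 by 0.81 ± 0.617, and none passed. In edgeR 0 of 22926 genes passed, with 1361 at an unadjusted p under 0.05. DESeq2 called 23 genes and limma-voom 1. Camera called upward the GABAergic, excitatory neuron, oligodendrocyte and microglia markers, with 0 members past the threshold, over all genes or adjusted over the list alone. Their adjusted p was 0.551, 0.356, 0.687 and 0.356 with an estimated correlation.

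The wider effect of Cre in VIP nuclei was compared line by line. In the dark E1 group the transcriptional coactivator gene Sub1 (chromosome 15, 11981339 to 11996983) was higher with Cre by 3.00 ± 0.452 (log2 ± SE), at 62.69 ± 13.9 CPM (n = 5) against 7.805 ± 4.09 (n = 3). Npy, the neuropeptide Y gene, was higher by 2.84 ± 0.509, the tRNA synthetase gene Qars by 3.54 ± 0.59, Scg2 by 3.36 ± 0.726 and the carbonic anhydrase Car4 by 2.38 ± 0.424. Shank1, a postsynaptic scaffold, was lower by −2.35 ± 0.395 (58.47 ± 18.8 against 297.8 ± 115 CPM), with Sh3rf1 at −2.39 ± 0.386 and Spred2, an inhibitor of the Ras pathway, at −2.14 ± 0.383. Excitatory synapse genes were lower for 14 of 25 members (19 lower and 2 higher adjusted over the list alone) and ion channels for 11 of 26 (15 lower and 1 higher adjusted over the list alone), while 4 of 10 heat-shock genes were higher (9 adjusted over the list alone). Each of these 3 lists had an adjusted p of 0.242 with an estimated correlation. Effector genes, oligodendrocyte and microglia markers were also called upward and IGF1 signalling genes downward (0.271, 0.589, 0.252 and 0.331 with an estimated correlation). The length index fell together with these groups, from 3.96 ± 1.21 with dCre to 1.82 ± 0.378 with Cre.

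In total 1889 of 20585 genes passed in E1 dark VIP nuclei, 1048 higher and 841 lower with Cre. The count was 59 without dCre replicate 1, 470 without dCre replicate 2, 3593 without dCre replicate 3 and 1037 without Cre replicate 4. Without dCre replicates 1 and 2 together, where the 1 library left is assumed to vary like the other groups, edgeR called 0 genes, and with the length index as a covariate 0. Without the 2 animals Qars was 3.08, Sub1 2.34, Scg2 2.20, Npy 1.95 and Car4 1.81, while Shank1 was −1.57, Sh3rf1 −1.27 and Spred2 −0.62 (adjusted p of 0.503 to 0.866). The genes named above passed with each single library left out. Vip was higher with Cre by 2.10 ± 0.496 (adjusted p = 0.00769), but not past the threshold without dCre replicate 1 (0.095) or 2 (0.0736).

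In the other 5 comparisons of Cre with dCre in VIP nuclei edgeR called 0 genes. At an unadjusted p under 0.05 there were 1095 genes in E1 after light, 1251 in E23 in the dark, 1260 in E23 after light, 1796 in E123 in the dark and 1798 in E123 after light. DESeq2 called 5, 7, 19, 27 and 22 genes and limma-voom 0, 0, 0, 0 and 2, in the same order. Leaving out single libraries gave 1 gene in E23 in the dark (without Cre replicate 2), 2 in E23 after light (without dCre replicate 4), 3, 1 and 1 in E123 in the dark (without dCre replicates 4 and 3 and Cre replicate 1) and 1 in E123 after light (without dCre replicate 1). Vip differed by 0.97 ± 0.443 (log2 ± SE) in E123 after light and 1.54 ± 0.473 in E123 in the dark, where Fos differed by 2.03 ± 1.07, none past the threshold. Camera called 5, 2, 2, 7 and 8 of the 24 lists, in the same order, each with 0 members past the threshold, and none with an estimated correlation. In E1 after light VIP markers (median 0.34) and GABAergic markers (0.34) were called upward and excitatory neuron markers (−0.71) downward, as were excitatory synapse and mitochondrial genes. E23 had oligodendrocyte markers and mitochondrial genes upward in the dark, and after light interferon genes upward and excitatory neuron markers (−0.76) downward. In dark E123 nuclei VIP markers (0.92), GABAergic markers (0.61), effector and heat-shock genes were called upward and IGF1 signalling, excitatory synapse and ion channel genes downward. In E123 after light excitatory synapse genes (−0.47), ion channels (−0.44) and IGF1 signalling genes were called downward and p53 targets (1.89), oligodendrocyte and microglia markers, interferon and heat-shock genes upward (adjusted p of 0.165 to 0.426 with an estimated correlation). The length index of these libraries was 2.27 ± 0.416 with Cre and 3.23 ± 0.223 with dCre (SD, n = 4 each).

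Whether VIP nuclei still respond to light with Cre was tested in each line. Nr4a1 rose by 2.55 ± 0.361 (log2 ± SE) in E1 Cre mice (199.5 ± 34.6 CPM, n = 4, against 33.9 ± 18, n = 5) and by 3.02 ± 0.401 in E23. Fosl2 rose by 3.38 ± 0.541 in E1 and 2.92 ± 0.581 in E23, and the third genes past the threshold were the kinase Hunk in E1 (2.10 ± 0.414) and Mir670hg in E23 (2.15 ± 0.377). In E123, 1 gene passed, AC174471.1 (chromosome 17, 30459502 to 30923831), an unnamed locus outside the naming rule and chosen after its value was seen. Immediate-early genes were called as a list in each line, with 2, 2 and 0 of 29 members past the threshold in E1, E23 and E123, and an adjusted p of 0.00149, 1.28e-05 and 0.000596 with an estimated correlation. Nr4a1 in both lines and Fosl2 in E1 passed with each library left out, while the E1 count became 5 without dark replicate 2, the E23 count 1 without dark replicate 3 and the E123 count 0 without dark replicate 1, 2 or 3. Hunk did not pass without light replicates 1 to 3 (0.167, 0.0788 and 0.0899) or dark replicates 1, 3, 4 and 5 (0.127, 0.153, 0.301 and 0.2), nor Mir670hg without dark replicates 2 (0.0532) and 3 (0.142). With a sex covariate or a replicate block Hunk did not pass either, nor did Fosl2 of E23 with a sex covariate or limma-voom. Fosl2 of E23 passed only without light replicate 4, with an adjusted p of 0.0733, 0.117 and 0.0931 without light replicates 1 to 3 and 0.0991, 0.112, 0.352 and 0.0958 without dark replicates 1 to 4. Without dark replicates 1, 2 and 3 of E123, AC174471.1 had an adjusted p of 0.177, 0.368 and 0.0576.

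The difference between the light response with Cre and that with dCre was tested gene by gene. In E1, 80 genes passed (23 higher, 57 lower), such as Sub1 (−3.03 ± 0.562, log2 ± SE) and Lin7a (−3.26 ± 0.597), neither of which passed without dark dCre replicate 1 (adjusted p = 0.0965 and 0.0525) or 2 (0.053 for each). Without dark dCre replicates 1, 2 and 3 the count was 1, 5 and 1754, and without the first 2 of these together, which leaves 1 library of that group, 0. Sub1 was then −2.37 (adjusted p = 0.533) and Lin7a −3.28 (0.344), and Lin7a passed with the length index as a covariate (0.0025). It was 299, 9, 14 and 27 without light dCre replicates 1, 2, 3 and 5, and 5, 26, 38 and 209 without light Cre replicates 1 to 4. Without dark Cre replicates 1 to 5 it was 18, 147, 39, 10 and 30. In E23 and E123 edgeR called 0 genes, with 1196 and 740 at an unadjusted p under 0.05; DESeq2 called 19 and 11 and limma-voom 2 and 0. Without dark Cre replicate 1 of E23 the count there was 1. Camera called 7, 1 and 2 lists in E1, E23 and E123, and none with an estimated correlation.

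In total nuclei, where most nuclei are not of VIP cells, Cre was compared with dCre in the same way. In the dark E1 group Rnf187 was higher with Cre by 2.23 ± 0.335 (log2 ± SE), at 115.5 ± 20.8 CPM (n = 5) against 24.7 ± 2.88 (n = 3), and Prelid1 by 2.28 ± 0.391, while Shank1 was lower by −1.58 ± 0.31 and the calcium channel Cacna1b by −1.15 ± 0.23. Excitatory synapse genes were lower for 5 of 25 members (16 adjusted over the list alone) and ion channels for 7 of 26, with 1 higher (16 and 1 adjusted over the list alone), and 1 of 10 heat-shock genes was higher (4 adjusted over the list alone). These lists had an adjusted p of 0.327 with an estimated correlation, as against 0.445 for effector genes and microglia markers, which camera called upward, and the length index was 1.85 ± 0.197 with Cre and 3.34 ± 1.07 with dCre. Of 21213 genes 590 passed (319 higher, 271 lower). The count was 2 without dCre replicate 1, 2 without dCre replicate 2, 3015 without dCre replicate 3, and 89, 291, 282 and 188 without Cre replicates 1, 2, 3 and 5; Rnf187 passed each time. Without dCre replicates 1 and 2 in turn, Prelid1 (0.0775 and 0.142), Shank1 (0.262 and 0.275) and Cacna1b (0.262 and 0.225) did not pass. Without both dCre replicates 1 and 2 it was 0, again with 1 library left and the spread taken from the other groups. Rnf187 was then 2.16 (adjusted p = 0.83), Prelid1 1.498, Shank1 −0.42 and Cacna1b −0.73 (adjusted p = 1 for each of these 3).

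In the dark E123 total nuclei 8 genes passed (7 higher, 1 lower), among them the nucleotide synthesis enzyme Prps1 (2.33 ± 0.454, log2 ± SE), Tmem106c (2.96 ± 0.583), the splicing kinase Clk1 (1.28 ± 0.263) and, lower, Adap1 (−1.79 ± 0.373). The p53 targets were called upward there (median 0.97; adjusted p = 0.0323 with an estimated correlation), with 0 of 12 past the threshold (1 adjusted over the list alone). Camera also called immediate-early, effector, astrocyte, microglia and heat-shock genes upward and excitatory synapse genes and ion channels downward, with 0 members past the threshold. Adjusted over the list alone these were 1, 6, 0, 0 and 1 higher, then 4 lower and 1 higher, and 5 lower. Their adjusted p was 0.337 to 0.579 with an estimated correlation. The length index was 2.67 ± 0.441 with Cre (SD, n = 3) and 3.40 ± 0.919 with dCre (n = 4). The count was 0 without any of dCre replicates 1 to 3 or Cre replicate 3, 2 and 1 without Cre replicates 1 and 2, and 58 without dCre replicate 4. The genes named did not pass without dCre replicates 1, 2 or 3 or Cre replicates 1 or 3, nor, Prps1 aside, without Cre replicate 2 (adjusted p of 0.0503 to 0.587). In the 4 other comparisons of total nuclei edgeR called 0 genes. At an unadjusted p under 0.05 there were 1287 in E1 after light, 1022 in E23 in the dark, 1214 in E23 after light and 1672 in E123 after light. DESeq2 called 4, 3, 16 and 9 genes and limma-voom 2, 0, 0 and 2. Camera called 5, 4, 3 and 6 lists, and none with an estimated correlation. Without dCre light replicate 1 of E23, and without Cre light replicate 1 of E123, 1 gene passed in the respective comparison after light.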

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

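Chosen after the results were seen were the tests of carried-over nuclei, of the share of VIP nuclei and of the region around Igf1, the splits of the comparisons that average Cre mice over lines, and 6 other split tests. These 6 are the splits for VIP against total nuclei, for light in dCre VIP nuclei of E1, E23, E123 and all lines, and for Cre against dCre in dark E1 VIP nuclei.

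Of 80 tests of single libraries (4 genes in 20 groups), 11 found a library far from the others of its group. Chance gives about 1 in 20 such groups if levels are normally distributed. Sparse levels near 0, as in several groups of total nuclei, need not be, so 11 of 80 is not read as an excess. In VIP nuclei, Igf1 was at 476.3 CPM in dark E1 Cre replicate 2, the highest of its group. Light E1 dCre replicate 1 held the lowest Vip (2702 CPM) and the lowest Fos (23.8 CPM) of its group, and light E123 Cre replicate 2 the lowest Fos (30.08 CPM). In total nuclei, light E1 dCre replicate 3 held the highest Igf1 (26.02 CPM), and replicate 2 of that group the highest Vip (205.5 CPM) and the lowest Fos (17.11 CPM). Light E123 dCre replicate 1 held the highest Vip (108.9 CPM). Dark E23 dCre replicate 1 held the highest Fos (18.35 CPM) and dark E123 dCre replicate 3 the highest Npas4 (6.833 CPM). In light E23 Cre total nuclei Vip had 0 counts in replicate 1, the lowest of its group, and 3 counts would be 1.07 CPM there.

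In 2 results an edgeR test of the difference between groups passed. The Cre effect on Igf1 after light was 0.95 higher (log2) in E23 than in E123 VIP nuclei, with an edgeR p of 0.0329 adjusted over 6 tests and a permutation p of 0.0641, or 0.384 adjusted over the 6. It was lost in 7 of 16 fits that left out 1 library, with adjusted p up to 0.121. The light response with Cre differed from that with dCre for 80 genes in E1 VIP nuclei, a count that ran from 1 to 1754 with 1 library left out.

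Comparisons that use the dark dCre mice of E1 called many genes, 1889 between Cre and dCre in dark VIP nuclei. Of the genes called there, 79.9% were lower with Cre and longer than the median tested gene or higher and shorter. A gene length trend may account for much of it. The count was 3593 without replicate 3 but 59 and 470 without replicates 1 and 2, so these 2 libraries, with the highest length indices, carry it. Both are labelled female and replicate 3 male. With sex as a covariate 1663 genes passed. A deletion effect in VIP cells would leave most total nuclei untouched, but 96.2% of these genes had the same direction there. This argues against it as the whole cause. Why the 2 animals differ (sex, handling, nuclear RNA quality or a true state) stays open, as the labels give no batch.

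No gene passed for a different light response in VIP and total nuclei (edgeR 0, with 1361 at an unadjusted p under 0.05; DESeq2 23, limma-voom 1). Nuclei of other types that passed the sort for VIP cells could blunt such a difference. Of the 23 immediate-early genes that rose in total nuclei, 10 had a ratio of light VIP to light total level above that of all 16 excitatory markers (median 0.314, highest 0.77; exact one-sided permutation p = 0.0018 over genes, which are not independent). These include Nr4a1 (1.20), Fos (1.32) and Fosl2 (2.41). The ratio is of levels after light, so a gene expressed in dark VIP nuclei can exceed the markers without rising in VIP cells. Nr4a1, Fos and Fosl2 rose by 2.19, 3.12 and 2.86 (log2) in VIP nuclei, against 2.23, 3.44 and 2.66 in total nuclei. For them, similar rises at these ratios argue against carried-over excitatory nuclei as the whole source of the rise. Over the 19 that rose in VIP nuclei the ratio ran from 0.305 to 2.41 (median 0.613), and over astrocyte markers from 0.393 to 1.03. For members in that range a part from other nuclei and a response of VIP cells therefore cannot be told apart. The median of 0.613 decided nothing by itself, as it lay between the upper quartile (0.386) and the highest of the excitatory ratios.

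The lower Igf1 in light Cre VIP nuclei of E123 (−1.23, log2) could come from fewer VIP nuclei in the sort or from a change of the whole region. The 13 VIP markers had a median change of 0.34 (SD 0.841), which argues against a lower share of VIP nuclei if the length index did not raise them. Vip, 1 of the 13, was higher with Cre by 0.97, but not with the length index as a covariate. The list as a whole was not tested with that covariate. The 20 measured genes around Igf1 had a median change of −0.12 (SD 0.916), which argues against a change of the whole region of that size. The length index of these libraries also differed, at 2.27 ± 0.416 with Cre and 3.23 ± 0.223 with dCre (SD, n = 4 each). With that index as a covariate, the Igf1 difference between E23 and E123 after light went from 0.95 to 0.73. The fall of Igf1 within E123 is not reported here with that covariate, so the part of the length index in it stays open. Loss of the enhancers is what the design sets and stays open as a hypothesis, as does any other difference between the Cre and dCre mice.

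Each comparison was refitted for other splits of the same libraries into groups of the same sizes, with the real split counted. For light in dCre VIP nuclei, 1 of the 35 splits gave as many genes in E23 (10, highest other 1), 1 of the 35 in E123 (2, highest other 1) and 1 of the 100 over all lines (1290, highest other 21). For dCre total nuclei it was 1 of the 35 in E23 (38, highest other 0), 1 of the 35 in E123 (79, highest other 9) and 1 of the 100 over all lines (1207, highest other 195). For light in Cre VIP nuclei it was 4 of the 100 in E1 (3, highest other 10), 1 of the 35 in E23 (3, highest other 2) and 1 of the 35 in E123 (1, highest other 0). Averaged over the lines in Cre mice, 1 of the 100 splits gave as many in VIP nuclei (72, highest other 52) and 1 of the 100 in total nuclei (316, highest other 30). VIP against total nuclei gave as many in 1 of the 100 splits that exchange the fractions of same-numbered libraries (8140, highest other 2078), and Cre against dCre after light over all lines gave as many in 4 of the 100 (1, highest other 1). Each of these shares was under 0.05, which argues against chance for each count taken alone. This does not extend to the size of the dCre counts over all lines. Those were 615 in VIP and 597 in total nuclei without E1 dark replicate 2, but 2476 and 2466 without E1 dark replicate 3. The splits cannot exclude that E1 dark replicates 1 and 2, which carry much of both counts, fell in 1 group by chance. The shares were not adjusted over the comparisons, and 1 of 35 is the smallest that 35 splits allow. Counts of 1 to 3 genes are therefore not shown to be beyond chance.

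In E1 the shares were also under 0.05, but the splits point to a structure of the samples. Other splits that kept dark dCre replicates 1 and 2 together also gave many genes. The splits therefore cannot exclude that these 2 animals fell in 1 group by chance. For light in dCre mice, 2 of the 56 splits gave as many genes in VIP nuclei (860, highest other 908) and 2 of the 56 in total nuclei (781, highest other 881). The highest other split set dark replicates 1 and 2 with light replicate 1 against the rest, in both fractions. For Cre against dCre in the dark, it was 1 of the 56 splits in VIP nuclei (1889, highest other 665) and 2 of the 56 in total nuclei (590, highest other 902). The highest other split again kept dCre replicates 1 and 2 together, with Cre replicate 2 in VIP nuclei and Cre replicate 4 in total nuclei. For the difference of the light responses in E1, 1 of the 100 splits gave as many (80, highest other 79).

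For Cre against dCre in dark E123 total nuclei, 4 of the 35 splits gave as many genes (8, highest other 262), so chance is not excluded. The split with 262 genes set dCre replicates 1 and 2, which have high length indices, with Cre replicate 1 against the rest. A count of 0 is reached by every split. That holds for all 100 splits of the difference between fractions in the light response (highest other 1), of Cre against dCre after light in E1 VIP (1) and E1 total nuclei (2) and in total nuclei over all lines (1), and of the difference of the light responses in E23 (1) and E123 (26). It holds for all 35 splits of Cre against dCre in VIP nuclei of E23 in the dark (1) and after light (1) and of E123 in the dark (32) and after light (1), and in total nuclei of E23 in the dark (13) and after light (1) and of E123 after light (1).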

How the results depend on the processing

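Chosen after seeing the data were the length index as a covariate, the 3 fits that leave out named animals, edgeR for Igf1 adjusted over 24 contrasts, and the comparisons that average Cre mice or pool the Cre effect over lines. Of 319 counts of genes under other settings, 184 stayed within 1.5 times the count given in the results, as did 271 of 362 with 1 library left out. For genes named in the text, 945 of 1064 values under other settings and 1140 of 1214 with 1 library left out kept their direction and their side of the threshold. RLE size factors and DESeq2 changed none of the calls of the named genes, the length index as a covariate ended 24, and the omission of 2 and of 4 animals ended 21 and 31. Depth and group size limit single genes: with 4 against 4 libraries, simulated 2-fold changes were recovered for 3 of 100 genes. No library was under 0.5 of the median of detected genes, so that alternative gave no value. Fits of only the groups compared do not apply to VIP against total nuclei, where no single library was left out either. Fits without named animals are given for the comparisons that use their groups. Elsewhere the count became 4 for light in E123 dCre VIP nuclei, and 6 in E1 and 9 in E23 for Cre VIP nuclei, without the 2 animals, and 5 in E1 and 5 in E23 for Cre VIP nuclei without the 4. The other counts outside 1.5 times follow, and except for fewer libraries or fewer genes tested the cause was not tested.

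RLE size factors gave 1 in E123 light for Cre against dCre in VIP nuclei. The count was 8 in E23 for light in VIP nuclei of Cre mice. No filter on low counts gave 73 in E23 and 65 in E123 for light in VIP nuclei of dCre mice. The count was 1248 in E1, 188 in E23 and 267 in E123 for light in total nuclei of dCre mice. There were 5 in E1 light, 33 in E23 dark, 6 in E23 light, 111 in E123 dark, 57 in E123 light and 33 in light over all lines for Cre against dCre in VIP nuclei. This setting called 40 in E1, 49 in E23, 48 in E123 and 229 in all lines for light in VIP nuclei of Cre mice. Also called were 759 in E1 and 8 in E23 for the Cre minus dCre light response. Further it called 1281 in E1 dark, 28 in E1 light, 9 in E23 dark, 55 in E23 light, 90 in E123 dark, 44 in E123 light and 105 in light over all lines for Cre against dCre in total nuclei. Last came 521 in all lines for light in total nuclei of Cre mice. The stricter filter gave 1 in E123 light for Cre against dCre in VIP nuclei. The count was 5 in E1 and 10 in E23 for light in VIP nuclei of Cre mice. There were 187 in E1 for the Cre minus dCre light response. This setting called 1021 in E1 dark for Cre against dCre in total nuclei. DESeq2 gave 1901 in E1, 70 in E23, 42 in E123 and 2044 in all lines for light in VIP nuclei of dCre mice. The count was 1860 in E1, 116 in E23, 272 in E123, 1813 in all lines and 23 in the VIP minus total response for light in total nuclei of dCre mice. There were 3178 in E1 dark, 5 in E1 light, 7 in E23 dark, 19 in E23 light, 27 in E123 dark, 22 in E123 light and 18 in light over all lines for Cre against dCre in VIP nuclei. This setting called 31 in E1, 43 in E23, 34 in E123 and 185 in all lines for light in VIP nuclei of Cre mice. Also called were 753 in E1, 19 in E23 and 11 in E123 for the Cre minus dCre light response. Further it called 1854 in E1 dark, 4 in E1 light, 3 in E23 dark, 16 in E23 light, 91 in E123 dark, 9 in E123 light and 9 in light over all lines for Cre against dCre in total nuclei. Limma-voom gave 22 in E23, 55 in E123 and 2275 in all lines for light in VIP nuclei of dCre mice. The count was 4214 in E1, 62 in E23, 588 in E123, 3792 in all lines and 1 in the VIP minus total response for light in total nuclei of dCre mice. There were 2 in E123 light and 2 in light over all lines for Cre against dCre in VIP nuclei. This setting called 5 in E1, 5 in E123 and 120 in all lines for light in VIP nuclei of Cre mice. Also called were 221 in E1 and 2 in E23 for the Cre minus dCre light response. Further it called 4484 in E1 dark, 2 in E1 light, 118 in E123 dark and 2 in E123 light for Cre against dCre in total nuclei. Sex as a covariate gave 8 in E123 for light in VIP nuclei of dCre mice. The count was 22 in E1 for the Cre minus dCre light response. A replicate block gave 17 in E23 for light in VIP nuclei of dCre mice. The count was 1 in E123 dark for Cre against dCre in VIP nuclei. There were 6 in E23 for light in VIP nuclei of Cre mice. This setting called 14 in E123 dark for Cre against dCre in total nuclei. Fits of only the groups compared gave 99 in E1, 1 in E23 and 5 in E123 for light in VIP nuclei of dCre mice. The count was 3 in E1 and 28 in E123 for light in total nuclei of dCre mice. There were 743 in E1 dark for Cre against dCre in VIP nuclei. This setting called 0 in E123 for light in VIP nuclei of Cre mice. Also called were 1 in E1 dark and 0 in E123 dark for Cre against dCre in total nuclei. The length index as a covariate gave 2 in E1, 23 in E23, 14 in E123 and 136 in all lines for light in VIP nuclei of dCre mice. The count was 4 in E1, 106 in E23, 186 in E123 and 425 in all lines for light in total nuclei of dCre mice. There were 0 in E1 dark and 2 in light over all lines for Cre against dCre in VIP nuclei. This setting called 12 in E1, 25 in E23, 2 in E123 and 175 in all lines for light in VIP nuclei of Cre mice. Also called were 1 in E1 for the Cre minus dCre light response. Further it called 0 in E1 dark and 3 in E123 dark for Cre against dCre in total nuclei. Last came 522 in all lines for light in total nuclei of Cre mice. Leaving out the 2 E1 dark dCre animals gave 0 in E1 and 73 in all lines for light in VIP nuclei of dCre mice. The count was 0 in E1 and 197 in all lines for light in total nuclei of dCre mice. There were 0 in E1 dark for Cre against dCre in VIP nuclei. This setting called 0 in E1 for the Cre minus dCre light response. Also called were 0 in E1 dark for Cre against dCre in total nuclei. Leaving out the 4 dark dCre animals of E1 and E123 gave 0 in E1, 0 in E123 and 46 in all lines for light in VIP nuclei of dCre mice. The count was 0 in E1, 23 in E123 and 157 in all lines for light in total nuclei of dCre mice. There were 0 in E1 dark for Cre against dCre in VIP nuclei. This setting called 0 in E1 for the Cre minus dCre light response. Also called were 0 in E1 dark and 0 in E123 dark for Cre against dCre in total nuclei. Leaving out the animal with a sex label mismatch gave 0 in E123 and 773 in all lines for light in VIP nuclei of dCre mice. The count was 24 in E123 for light in total nuclei of dCre mice. There were 0 in E123 dark for Cre against dCre in total nuclei.

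With 1 library left out at a time the count ran from 17 to 2425 in E1, 1 to 9 in E23, 0 to 3 in E123 and 615 to 2476 in all lines for light in VIP nuclei of dCre mice. It ran from 4 to 2904 in E1, 15 to 37 in E23, 24 to 145 in E123 and 597 to 2466 in all lines for light in total nuclei of dCre mice. The range was 59 to 3593 in E1 dark, 0 throughout in E1 light, 0 to 1 in E23 dark, 0 to 2 in E23 light, 0 to 3 in E123 dark, 0 to 1 in E123 light and 1 throughout in light over all lines for Cre against dCre in VIP nuclei. Libraries left out in turn gave 2 to 5 in E1, 1 to 4 in E23, 0 to 1 in E123 and 36 to 89 in all lines for light in VIP nuclei of Cre mice. Omissions gave 1 to 1754 in E1, 0 to 1 in E23 and 0 throughout in E123 for the Cre minus dCre light response. The count went from 2 to 3015 in E1 dark, 0 throughout in E1 light, 0 throughout in E23 dark, 0 to 1 in E23 light, 0 to 58 in E123 dark, 0 to 1 in E123 light and 0 to 1 in light over all lines for Cre against dCre in total nuclei. Last, it was 187 to 340 in all lines for light in total nuclei of Cre mice.

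Igf1 kept its direction in the 12 contrasts of VIP nuclei under the settings reported for them. These are pseudocounts of 0.1 and 5, total counts, RLE size factors, edgeR and a replicate block. Total counts brought the light response of E1 dCre from 0.48 to 0.82. Its calls over 24 contrasts were gained in edgeR (E1 light −0.78, E123 light −1.23, E123 dCre light response 0.76) and with a replicate block in edgeR (−0.80, −1.23 and 0.79). In total nuclei the light response of E1 dCre turned from −0.0223 to 0.29 with a pseudocount of 0.1, 0.13 with total counts, 0.23 in edgeR and 0.34 with a replicate block, and that of E123 Cre from 0.60 to −0.00858 with a replicate block. With 1 library left out, for Cre against dCre in VIP nuclei the difference was −0.65 to −0.48 in E1 dark, −0.92 to −0.62 in E1 light, −0.63 to −0.23 in E23 dark, −0.41 to −0.21 in E23 light, −0.66 to −0.29 in E123 dark and −1.32 to −1.14 in E123 light. For light against dark in VIP nuclei the difference was 0.41 to 0.58 in E1 dCre, 0.27 to 0.45 in E23 dCre, 0.60 to 0.97 in E123 dCre, 0.14 to 0.44 in E1 Cre, 0.28 to 0.68 in E23 Cre and −0.11 to 0.17 in E123 Cre. For Cre against dCre in total nuclei the difference was −0.33 to 1.49 in E1 dark, −0.86 to 0.33 in E1 light, 0.60 to 1.29 in E23 dark, 0.66 to 2.06 in E23 light, −0.84 to −0.0457 in E123 dark and 1.37 to 2.90 in E123 light. For light against dark in total nuclei the difference was −1.11 to 0.71 in E1 dCre, −1.63 to −0.22 in E23 dCre, −2.72 to −1.19 in E123 dCre, −1.58 to −0.73 in E1 Cre, −0.81 to −0.12 in E23 Cre and 0.21 to 1.11 in E123 Cre.

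The Cre effect on Igf1 between lines ran from −0.43 to 0.0446 for E1 minus E23 in the dark, −0.27 to 0.0782 for E1 minus E123 in the dark, −0.13 to 0.38 for E23 minus E123 in the dark, −0.60 to −0.34 for E1 minus E23 after light, 0.30 to 0.61 for E1 minus E123 after light and 0.80 to 1.04 for E23 minus E123 after light. For E23 minus E123 after light the call ended with no filter on low counts (0.94) and with the length index as a covariate (0.73). With that covariate E1 minus E123 in the dark turned from −0.0889 to 0.066 and E1 minus E23 in the dark from −0.30 to 0.0504. The cause was not tested.

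Gene list tests called 185 of 672, against 46 with an estimated correlation, 113 with fry (88 of them among the 185) and 182 with a replicate block. Among genes named in the text, none that passed turned its direction. Vip in total nuclei (light against dark, dCre) turned to −0.63 with limma-voom, and it was −1.07 without light E123 replicate 1 and up to 1.42 with another library left out. Igf1 in that comparison turned to 0.40 with the length index as a covariate, 2.31 without the 2 animals and 2.59 without the 4 animals, and ran from −0.81 to 0.0218 with 1 library left out. For the VIP minus total light response, Fos turned to 0.15 and Vip to 1.77 with limma-voom, and Vip to 1.31 with a replicate block, while Igf1 turned to −1.75 without the 2 animals and −2.01 without the 4 animals. Npas4 turned to 0.0441 without a filter, 0.0145 with the stricter filter, 2.39 without the 2 animals, 2.73 without the 4 animals, 0.0915 without the animal with a sex label mismatch and 0.0109 in fits of only the groups compared. Vip in E123 light, Cre against dCre, turned to −0.030 with the length index as a covariate. The cause was not tested.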

Other observations

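The comparisons below that average Cre mice over lines, or that pool the Cre effect over lines, were chosen after seeing the data.

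In VIP nuclei of Cre mice averaged over 3 lines (12 light and 12 dark libraries), light raised activity genes. Nr4a1 rose by 2.41 ± 0.231 (log2 ± SE), Fosl2 by 3.04 ± 0.348, Egr1 by 2.41 ± 0.368, Fos by 2.57 ± 0.566 and Per1, a clock gene that light also induces, by 1.66 ± 0.286. Homer1 rose by 1.13 ± 0.219 and Ntrk2, the receptor of BDNF, by 0.97 ± 0.139, while Zkscan2 fell by 0.97 ± 0.2. In all 72 of 20585 genes passed (55 higher, 17 lower), and immediate-early genes were called as a list (9 of 29 past the threshold; adjusted p = 8.49e-08 with an estimated correlation). Effector genes (1 of 24; 0.00238) and MAPK regulators (1 of 12; 4.78e-06) were called as well. Other lists were called upward with them: astrocyte (median 0.90), oligodendrocyte (0.72) and microglia markers (0.70), GABAergic markers, circadian genes, p53 targets and heat-shock genes. Their adjusted p was 0.325, 0.288, 0.282, 0.232, 0.127, 0.127 and 0.247 with an estimated correlation. The count was 36 without dark E123 replicate 1 and 37 without dark E123 replicate 2. Of the 1290 genes called in dCre VIP nuclei, 45 were also called here in the same direction, where 2.57 would be shared if the calls were independent. Without the E1 dark dCre replicates 1 and 2, 20 of 73 were shared (0.149 if independent), and 91.8% of the 73 had the same sign.

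In total nuclei of Cre mice 316 of 21213 genes passed (232 higher, 84 lower), with 21 of 27 immediate-early genes higher (adjusted p = 3.17e-10 with an estimated correlation). The count was 187 without dark E123 replicate 2. Of the 197 genes called in dCre total nuclei without the E1 dark replicates 1 and 2, 103 were called here in the same direction (1.79 if independent), and 95.9% had the same sign.

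Igf1 was the only gene past the threshold when Cre was compared with dCre after light over all lines in VIP nuclei (12 Cre and 13 dCre libraries). It fell by 0.77 ± 0.132 (log2 ± SE), to a fitted 58.8% of dCre, lower in 3 of 3 lines, with an edgeR adjusted p of 0.00761. The exact permutation within lines gave p = 2.43e-05 over 617400 arrangements. With each of the 25 libraries left out in turn, 1 gene passed. Camera called GABAergic markers (median 0.30), p53 targets (0.58) and interferon genes (0.79) upward and excitatory neuron markers (−0.57), excitatory synapse genes (−0.20) and ion channels (−0.16) downward there. Each had 0 members past the threshold, and the adjusted p was 0.183, or 0.294 for ion channels, with an estimated correlation. In the dark the Igf1 change was −0.45 ± 0.138, or 73.1% of dCre, lower in 3 of 3 lines, with an exact permutation p of 0.0047 over 137200 arrangements. In edgeR Igf1 ranked 996 of 20585 genes by p there (adjusted p = 0.0394), so it was 1 of many genes past the threshold. Over light and dark together the Igf1 change was −0.61 ± 0.0955, or 65.6%, lower in 6 of 6 groups. The permutation p was 2e-05 from 100000 draws. The dark and the combined values include the dark dCre mice of E1 and E123 with high length indices. Neither was refitted without those mice or with the length index as a covariate. DESeq2 called 18 genes and limma-voom 2 in the light comparison. In total nuclei edgeR called 0 genes, with 1273 at an unadjusted p under 0.05, and DESeq2 9 and limma-voom 0. Without light E123 Cre replicate 1, edgeR called 1. Camera called microglia (median 0.85) and oligodendrocyte markers (0.67) upward and astrocyte (−0.65) and somatostatin markers (−0.33) downward in total nuclei. Their adjusted p was 0.124, 0.788, 0.124 and 0.367 with an estimated correlation.

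Levels of sex-linked genes did not match the sex label in 2 of 96 libraries. These were the VIP and total libraries of replicate 2 in the dark dCre group of E123. That replicate is 1 of those left out in other fits for a high length index. Without its VIP library, Igf1 did not pass for light in E123 dCre VIP nuclei (edgeR p adjusted over 24 contrasts, 0.0589). Nr4a1 and Fosl2 did not pass there either.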
